A study of Mus musculus with 80 samples.

How the data were processed

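RNA from the gastrocnemius, a calf muscle, of C57BL6/J mice was sequenced in 80 libraries, 41 from males and 39 from females. The hindlimbs had been unloaded for 24, 48, 72 or 168 h, or not at all (0 h). Each library was taken as one animal, with the sex and time that the sample labels give. No paired analysis was possible because the replicate numbers only follow the order of the sample records.

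The authors deposited one table per sex. The submitters' notes name STAR 2.7.8a, DESeq2, Partek and the builds mm10 and mm39, without saying which step used which. The deposited expression values are a signal, not read counts: although their sheet is called raw data, they are estimated reads per gene divided by one size factor per library. The median ratio of a library to the geometric mean over its table lay between 0.977 and 1.04 in females and between 0.992 and 1.02 in males, as median-of-ratios scaling leaves it. The tables hold 12853 genes for males and 11068 for females, and the lowest row maximum was 100.02 and 100.01, so genes that never reached about that level were absent. The authors' DESeq2 sheet, also deposited, gives for each time against 0 h a ratio and a p-value adjusted by FDR step up; 9 genes per sex have no number there. Enrichment sheets and partial copies of the DESeq2 sheet were not used.

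Within a library, many low values are whole multiples of one step, so the step is close to the value of a single read. Between 54.0% and 71.8% of the values with a signal from 2 to 120 were whole reads within 0.03 reads, where about 5.96% would be by chance. Dividing the signal by this step gave the estimated depth of each library, and in 5 simulated libraries the step was found with an error of at most 0.00132%. The depth was used to describe the libraries and in one alternative; whole counts were not recovered. Females had 5.57 to 50.5 M and males 18.0 to 49.7 M estimated reads per library.

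The plan was to test counts, with limma as the fallback if a table held none. Because the values are a normalized signal, limma 3.58.1 in R 4.3.3 was used on log2 of the value plus 1. One model per sex held all 5 groups, and a joint model of all 10 groups held the 10964 genes found in both tables. Variances were moderated with a trend on the mean and robustly, and p values were two-sided and adjusted by the Benjamini-Hochberg method over all genes tested. A gene was called at an adjusted p under 0.05. Each time was compared with 0 h within a sex, and the sex difference at a time was the female change minus the male change. Levels of males and females were never compared, because the sexes were normalized in separate tables. The direct comparisons of 72 h with 48 h and of 168 h with 72 h were added after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and the R package data.table (1.17.8), were used for the rest.

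The rule for named genes, the gene lists and the alternatives not given below as added were chosen before the data were examined. Named genes are the 4 highest and 4 lowest log2 changes among called genes with a mean of at least 5 ppm of the library's signal, with provisional symbols left out (5 and 5 for a sex difference). They also include 17 focus genes and up to 4 members of each list with the smallest p. A few genes that the rule names are not reported here. The gene lists, 20 in all, were atrophy ubiquitin ligases and FoxO targets, 26S proteasome, autophagy and lysosome, denervation and neuromuscular junction, p53 and growth arrest, nuclear oxidative phosphorylation, mitochondrially encoded genes, TCA cycle and fatty acid oxidation, mitochondrial biogenesis and dynamics, antioxidant and NRF2 response, slow and fast muscle fibre genes, extracellular matrix, ribosome biogenesis, IGF, mTOR and TGF-beta family signalling, heat shock and unfolded protein response, circadian clock, glucocorticoid response, cell cycle, and interferon response. The other 11 held markers of red blood cells, macrophages, neutrophils, lymphocytes, adipocytes, endothelial cells, fibro-adipogenic progenitors, tenocytes, Schwann cells, satellite cells and smooth muscle. Ddit4 stands in the atrophy, IGF and glucocorticoid lists, Cebpd and Klf15 in the atrophy and glucocorticoid lists, Eif4ebp1 in the atrophy and IGF lists, Psmd11 in the atrophy and proteasome lists, Mt2 in the antioxidant and glucocorticoid lists, and Per1 in the circadian and glucocorticoid lists. Lists were tested with limma camera, which compares a list's members with all other genes, with the correlation between members estimated. Its p was adjusted over the lists of a comparison. A preset correlation of 0.01 was an alternative.

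Genes were matched by the identifiers in the tables. Chromosome, start and end are those of the tables: 2.29% of 12805 matched genes have the same start as in an mm10 annotation, and 98.3% have the same length when the last coordinate is read as exclusive. Positions are therefore given as of a build like mm39, and the end was set 1 base before the deposited stop. Transcript length was known for 99.8% of the genes of each table.

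Library sets were inferred from the index numbers in the sample titles, since no batch is labelled. By these, the male controls shared a set with the 168 h libraries and 2 of the 9 libraries at 72 h. The female controls shared one with the 48 h libraries. The other comparisons with 0 h were between sets. The alternatives were a threshold on the log2 change of 1, models of the compared groups alone, libraries thinned to one depth, leaving out the least correlated library of each group, the male 72 h libraries by set, leaving out the one male 48 h library of another set, and, for the correlations between the sexes, genes with a mean of at least 5 ppm. Added after seeing the data were a pseudocount of 10, a mean value of at least 50, quantile normalization, scaling to the library total, array weights, a covariate for each library's trend with transcript length, a tenocyte covariate, leaving out poorly correlated female libraries, and leaving out each library in turn.

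The test was tried on simulated libraries with known changes. Values were drawn from a normal distribution with each gene's mean and residual SD, independently for each gene and library. Unlike the real libraries, these hold no genes that move together, no library that stands apart and no library sets. Of 100 genes changed by 0.5 on the log2 scale, 59 to 70 were called in the male comparisons, 41 to 54 in the female ones and 25 to 40 in the tests of a sex difference. Of 100 genes changed by 1, these were 90 to 97, 83 to 91 and 73 to 82. Between 2 and 12 unchanged genes were called per comparison, and a list raised on purpose was called in all 12 comparisons, while in 2 of them (female 72 h and the sex difference at 168 h) 1 list that was not raised was called as well. Members of real lists can move together, which the simulated ones did not. The simulation therefore does not show how well the list test finds a real list that changes.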

Results

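RNA was measured by sequencing in the gastrocnemius, a mixed calf muscle used in standing and walking, of C57BL6/J mice. In hindlimb unloading the hind legs are kept off the ground, so that the calf muscles bear no weight and begin to waste. Unloading lasted 24, 48, 72 or 168 h, and control mice (0 h) were not unloaded. Males numbered 7 at 0 h, 8 at 24 h, 9 at 48 h, 9 at 72 h and 8 at 168 h, and females 8 at 0, 24, 48 and 72 h and 7 at 168 h. The study's own description gives 8 per group. Comparing each time with 0 h within a sex asks which genes change, and when, as a muscle loses its load. Comparing the changes of females and males asks whether the sexes differ at the onset of wasting.

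The estimated depth of male libraries was 28.3 ± 7.11 M reads (mean ± SD) at 0 h, 37.2 ± 2.97 at 24 h, 41.7 ± 3.63 at 48 h, 38.9 ± 3.39 at 72 h and 37.0 ± 9.44 at 168 h. Female libraries held 37.2 ± 10.6, 9.03 ± 2.02, 37.5 ± 6.85, 6.72 ± 1.34 and 17.8 ± 3.46 M at the same times, so the female 24 and 72 h libraries were the shallowest. The deposited signal summed to 33.1 to 39.4 M per male library and 12.8 to 19.3 M per female library. Xist, the long RNA that silences an X chromosome in females, was in the female table alone, above 0 in 39 of 39 libraries. The Y-linked genes Ddx3y, Uty, Eif2s3y and Kdm5d were in the male table alone, above 0 in 41 of 41.

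Some female libraries stood apart from their groups. The median Spearman correlation with the group's other libraries was under 0.95 in replicate 7 at 0 h (0.916), replicates 1 and 2 at 24 h (0.932 and 0.904), replicate 5 at 48 h (0.934), replicates 2 and 5 at 72 h (0.942 and 0.866) and replicate 7 at 168 h (0.947). Xist in these 7 libraries was 172 to 1564, and in the other 32 it was 1181 to 4274.

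**Figure D1:**
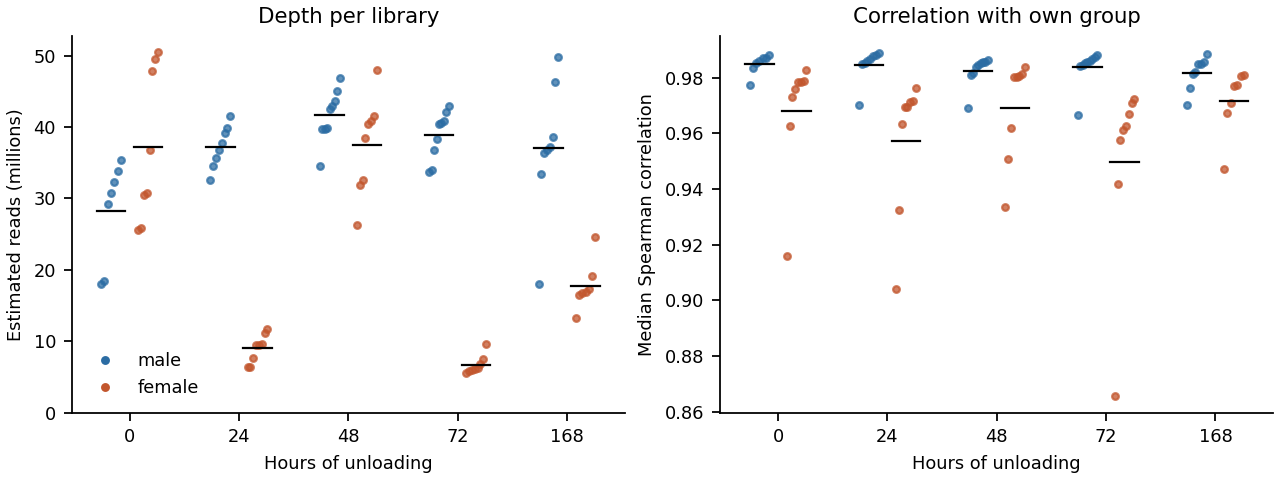
Estimated depth of each library (M reads, vertical axis) and its median Spearman correlation with the other libraries of its group (no unit, vertical axis) by sex and hours of unloading (h, horizontal axis), with bars at the means. Depth ranged from 5.57 to 50.5 M reads in females.

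Positions are on a build like mm39, which the files do not name with certainty. Fbxo32 (ENSMUSG00000022358) lies on chromosome 15 from 58039275 to 58078328, Trim63 (ENSMUSG00000028834) on chromosome 4 from 134042431 to 134056940, and Cdkn1a (ENSMUSG00000023067) on chromosome 17 from 29309950 to 29319701. Eif4ebp1 (ENSMUSG00000031490) lies on chromosome 8 from 27750357 to 27766702, Mt1 (ENSMUSG00000031765) on chromosome 8 from 94905710 to 94906955, and Col1a1 (ENSMUSG00000001506) on chromosome 11 from 94827050 to 94843868. Odf3l2 (ENSMUSG00000035963) and Rhobtb1 (ENSMUSG00000019944) lie on chromosome 10, from 79475360 to 79481572 and from 68987264 to 69127621. All are annotated as protein coding. Changes below are log2 changes ± the standard error of limma, and p values are limma's, adjusted over all genes. Unless a count is given, a gene named with a p for a change within one sex moved in the stated direction in every library of the group, relative to the mean of the controls.

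Many genes that tag and degrade muscle protein were higher in males after 24 h. Fbxo32 and Trim63, ubiquitin ligases that mark proteins of wasting muscle for breakdown, rose by 2.10 ± 0.33 (adjusted p = 1.1e-05) and 1.62 ± 0.29 (7.0e-05). Mean Fbxo32 went from 7905 ± 1605 (SD, n = 7) to 34881 ± 11566 (SD, n = 8). Subunits of the 26S proteasome, which digests the tagged proteins, rose with them, as Psmd8 did by 0.97 ± 0.12 (1.8e-07) and Psmd4 by 0.80 ± 0.11 (1.1e-06). The autophagy receptor Sqstm1 rose by 1.12 ± 0.14 (3.0e-07) and the autophagy kinase Ulk1 by 0.62 ± 0.11 (8.7e-05). Eif4ebp1, a brake on protein synthesis, rose by 1.42 ± 0.19 (1.1e-06), Ddit4, an inhibitor of mTOR, by 1.64 ± 0.42 (0.0029), and Cdkn1a, the cell cycle inhibitor p21, by 1.32 ± 0.27 (0.00029). The p53 targets Phlda3 and Eda2r rose by 1.11 ± 0.10 (8.5e-10) and 1.94 ± 0.31 (1.8e-05). Of the targets of the glucocorticoid receptor, Fkbp5 rose by 1.41 ± 0.21 (5.1e-06) and Cebpd by 1.73 ± 0.37 (0.00054), and so did the NRF2 target Nqo1, by 0.72 ± 0.11 (4.6e-06).

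The largest changes in males at 24 h were those of Depp1, a FoxO target, at 2.55 ± 0.45, of Chac1, a glutathione-degrading enzyme of the stress response, at 2.32 ± 0.45, of Pnmt, which makes adrenaline, at 2.25 ± 0.29, and of Pdk4, which blocks glucose oxidation, at 2.11 ± 0.50. Among lower genes, Zdhhc23, a palmitoyl transferase, fell by 1.80 ± 0.31, the transferrin receptor gene Tfrc by 1.79 ± 0.22, the water channel gene Aqp4 by 1.77 ± 0.29, and the histone gene H2bc6 by 1.70 ± 0.30. The mitochondrial coactivators Ppargc1a and Ppargc1b fell by 0.53 ± 0.10 (0.00019) and 1.29 ± 0.21 (1.7e-05). The growth factor binding protein Igfbp5 fell by 1.07 ± 0.24 (0.0008), the slow fibre gene Casq2 by 0.87 ± 0.21 (0.0016), and the collagen gene Col6a3 by 0.69 ± 0.17 (0.0016). Mt1, a metal-binding stress protein, was at 0.39 ± 0.25 (0.25, 7 of 8 libraries higher).

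Called genes in males at 24 h numbered 1896 higher and 1847 lower of 12853. With scaling to the library total, 1144 were higher and 2369 lower. By list, with counts adjusted over the list alone in parentheses, 14 of 22 atrophy genes rose and 1 fell (17 and 1), all 32 proteasome genes rose (32), 12 of 23 autophagy genes rose (14, with 1 lower), and 10 of 15 glucocorticoid response genes rose (13). Of 15 p53 genes 9 rose and 2 fell (9 and 2), of 22 antioxidant genes 12 rose (12), of 25 ribosome biogenesis genes 13 rose and 1 fell (14 and 1), and of 17 interferon genes 8 fell (11). No list passed camera, with adjusted p = 0.137 with an estimated correlation for the atrophy, proteasome, autophagy, p53 and glucocorticoid lists, 0.299 for the antioxidant and ribosome biogenesis lists, and 0.485 for the interferon list. Gadd45a, another growth arrest gene, rose by 0.68 ± 0.23 (0.023), and Mstn, which limits muscle size, by 0.45 ± 0.15 (0.019, 7 of 8 libraries). Without male 0 h replicate 4 the adjusted p of Gadd45a was 0.059, and without male 0 h replicate 5 that of Mstn was 0.061.

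After 48 h Fbxo32 was up in males by 2.31 ± 0.32 (1.5e-06) and Trim63 by 1.58 ± 0.28 (5.7e-05), and mean Fbxo32 was 42354 ± 19964 (SD, n = 9). Proteasome genes Psmd4 and Psmd8 rose by 0.94 ± 0.11 (3.3e-08) and 0.90 ± 0.11 (1.7e-07), Sqstm1 by 1.08 ± 0.13 (1.7e-07), and the lysosomal protease Ctsl by 0.81 ± 0.12 (3.7e-06). Fbxo31, another ubiquitin ligase subunit, rose by 0.61 ± 0.10 (2.0e-05), Eif4ebp1 by 1.52 ± 0.19 (1.7e-07) and Cdkn1a by 1.43 ± 0.26 (6.3e-05). Hdac4, which relays loss of nerve activity, rose by 0.79 ± 0.14 (2.9e-05), the acetylcholine receptor gene Chrna1 by 0.48 ± 0.12 (0.0018, 8 of 9 libraries), and Sln, an inhibitor of the calcium pump, by 1.08 ± 0.26 (0.0014). Of 17 genes of the denervation list 4 rose and 5 fell (4 and 5 adjusted over the list alone, adjusted p = 0.861 with an estimated correlation). The glucocorticoid target Fkbp5 rose by 1.21 ± 0.21 (2.5e-05).

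Casq2 and Casq1, calcium stores of slow and fast fibres, fell in males at 48 h by 1.21 ± 0.20 (2.1e-05) and 0.72 ± 0.16 (0.00058), the slow light chain gene Myl2 by 1.08 ± 0.34 (0.012), and the oxidative myosin gene Myh2 by 1.16 ± 0.35 (0.011). The fast myosin gene Myh1 rose by 0.93 ± 0.25 (0.0044, 8 of 9 libraries). Csrp3, a stretch sensor of the fibre, fell by 2.29 ± 0.45 (0.00019), Mdga1, a cell adhesion gene, by 2.25 ± 0.27 (1.1e-07), and Tfrc by 2.06 ± 0.21 (9.9e-09). The collagen genes Col15a1 and Col6a2 fell by 0.74 ± 0.17 (0.00072) and 0.74 ± 0.21 (0.0061), the chaperone gene Hsph1 by 0.62 ± 0.12 (0.00011, 8 of 9 libraries), and the mitotic kinase gene Aurka by 1.63 ± 0.18 (1.9e-08). The T cell marker Cd3e, the only lymphocyte marker measured, fell by 2.02 ± 0.47 (0.001), while the endothelial marker Cldn5 rose by 1.08 ± 0.21 (0.00015).

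At 48 h 2099 genes were higher and 1889 lower in males. Adjusted over all genes (and, in parentheses, adjusted over the list alone), 12 of 22 atrophy genes rose and 1 fell (14 and 1), all 32 proteasome genes rose (32), 15 of 23 autophagy genes rose (17), 9 of 15 glucocorticoid genes rose (11), and 8 of 15 p53 genes rose and 2 fell (10 and 2). Of 18 heat shock genes 4 rose and 9 fell (5 and 9), of 29 matrix genes 1 rose and 8 fell (1 and 8), of 17 interferon genes 9 fell (13), and of 4 smooth muscle markers 3 fell (3). The adjusted p = 0.149 with an estimated correlation for the atrophy, proteasome and autophagy lists, 0.167 for the p53 and glucocorticoid lists, 0.446 for smooth muscle, 0.47 for interferon and 0.861 for the heat shock and matrix lists.

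At 72 h the ubiquitin ligase genes of males were not called. Fbxo32 was at 0.56 ± 0.32 (0.28, 7 of 9 libraries higher), Trim63 at 0.28 ± 0.28 (0.6, 7 of 9) and Cdkn1a at 0.45 ± 0.26 (0.3, 8 of 9), and mean Fbxo32 was 12157 ± 3902 (SD, n = 9). Many proteasome genes were up, with Psmd8 at 0.77 ± 0.11 (1.7e-05) and Psmd2 at 0.52 ± 0.08 (4.1e-05), and so were Txnip, which inhibits glucose uptake, at 0.51 ± 0.12 (0.0052), and the autophagosome gene Map1lc3a, at 0.55 ± 0.10 (0.00015). Fabp3, which carries fatty acids, fell by 1.68 ± 0.24 (1.2e-05), Dlst, of the TCA cycle, by 0.31 ± 0.07 (0.0033), Bdh1, which burns ketone bodies, by 1.81 ± 0.34 (0.00053), and Casq2 by 1.18 ± 0.20 (0.00013). The chaperone genes Hsph1, Hspa8 and Cryab fell by 0.91 ± 0.12 (3.8e-06), 0.61 ± 0.10 (5.3e-05) and 1.07 ± 0.21 (0.00085). Mss51, a muscle mitochondrial regulator, rose by 2.02 ± 0.32 (6.4e-05), Nwd1 by 1.56 ± 0.21 (3.8e-06) and Ctxn3 by 1.08 ± 0.18 (0.00013), while the muscle noncoding RNA Lincmd1 fell by 2.29 ± 0.54 (0.0045). Fabp3-ps1, a near copy of Fabp3 whose reads are hard to assign, was at −1.89 ± 0.31.

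Higher genes in males at 72 h numbered 721 and lower genes 671. Of the 9 libraries, 2 belonged to the library set of the controls. With these 2 alone 516 genes were called, and with the other 7 alone 816, while array weights gave 2103. Among the 35 calls of named genes that ended with the 2 alone were those of Eif4ebp1 (0.85 ± 0.19, 0.0026), Myl2 (−1.65 ± 0.34, 0.0011), Myh2 (−1.44 ± 0.35, 0.006) and Sln (0.98 ± 0.26, 0.011), and 17 ended with the other 7 alone. Ppargc1a fell by 0.32 ± 0.10 (0.036), which was 0.091 without male 0 h replicate 1. By list (adjusted over the list alone in parentheses), 19 of 32 proteasome genes rose (26), 8 of 23 autophagy genes rose (10), 3 of 22 atrophy genes rose (3), 6 of 18 heat shock genes fell (9, with 2 higher), 4 of 30 TCA cycle and fatty acid genes fell (7), and 3 of 12 slow fibre genes fell (5). The adjusted p = 0.251 with an estimated correlation for the proteasome, autophagy and heat shock lists, 0.495 for the atrophy and slow fibre lists and 0.756 for the TCA cycle list. No matrix gene of 29 was called by limma, while 3 had an unadjusted p under 0.05. Without male 0 h replicate 7 Col15a1 (0.0373) and Col6a3 (0.0441) were called, and without male 72 h replicate 9 Col15a1 (0.0375) and Col4a1 (0.049989).

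After 168 h, a week without load, Fbxo32 was up in males by 1.41 ± 0.33 (0.0019) and Trim63 by 1.12 ± 0.29 (0.005). Fbxo32 stood at 103210 in replicate 8 and between 10544 and 24632 in the other 7 libraries, and leaving out any 1 library ended neither call. Txnip rose by 1.03 ± 0.13 (3.2e-07), Cdkn1a by 1.32 ± 0.27 (0.00047), Psmd8 by 0.79 ± 0.12 (5.6e-06), Mstn by 0.55 ± 0.15 (0.0058), the activin gene Inhbb by 1.23 ± 0.27 (0.0011), and the acetylcholine receptor gene Chrnb1 by 0.93 ± 0.12 (3.4e-07). Respiratory chain genes Ndufs1 and Uqcrc2 fell by 0.43 ± 0.09 (0.00056) and 0.35 ± 0.08 (0.0025), and Dlst, Hadh and Idh2, of the TCA cycle and fatty acid oxidation, by 0.46 ± 0.07 (2.0e-05), 0.50 ± 0.10 (0.00027) and 1.16 ± 0.22 (0.00029). Slow fibre genes Myl2 and Myl3 fell by 1.81 ± 0.34 (0.00024) and 1.79 ± 0.38 (0.00084), and Myh2 by 1.69 ± 0.36 (0.00087), while the fast fibre gene Actn3 rose by 0.66 ± 0.11 (3.4e-05). Hsph1 and Cryab fell by 0.88 ± 0.12 (2.5e-06) and 1.18 ± 0.22 (0.00018), Col15a1 by 0.88 ± 0.17 (0.00026), and the capillary receptor gene Kdr by 0.92 ± 0.18 (0.00025). The largest changes were those of Mss51 (2.58 ± 0.33), Arrdc2, an arrestin family gene (2.30 ± 0.38), Bdh1 (−2.25 ± 0.35) and the cardiac actin gene Actc1 (−2.23 ± 0.44). Col1a1, a main collagen, fell by 1.22 ± 0.41 (0.03, 7 of 8 libraries), which was 0.079 without male 0 h replicate 4.

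At 168 h 1418 genes were higher and 1479 lower in males, whose controls belong to the same library set. By list (adjusted over the list alone in parentheses), 20 of 32 proteasome genes rose (24), 8 of 22 atrophy genes rose and 1 fell (9 and 1), 11 of 15 glucocorticoid genes rose (12), 14 of 42 oxidative phosphorylation genes fell (15), 16 of 30 TCA cycle and fatty acid genes fell (22), 7 of 12 slow fibre genes fell (7), 4 of 18 heat shock genes rose and 11 fell (4 and 11), and 7 of 29 matrix genes fell (14, with 1 higher). The adjusted p = 0.369 with an estimated correlation for the glucocorticoid list, 0.421 for the atrophy list, 0.474 for the proteasome, TCA cycle and heat shock lists, 0.482 for the slow fibre list, and 0.588 for the oxidative phosphorylation and matrix lists.

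**Figure D2:**
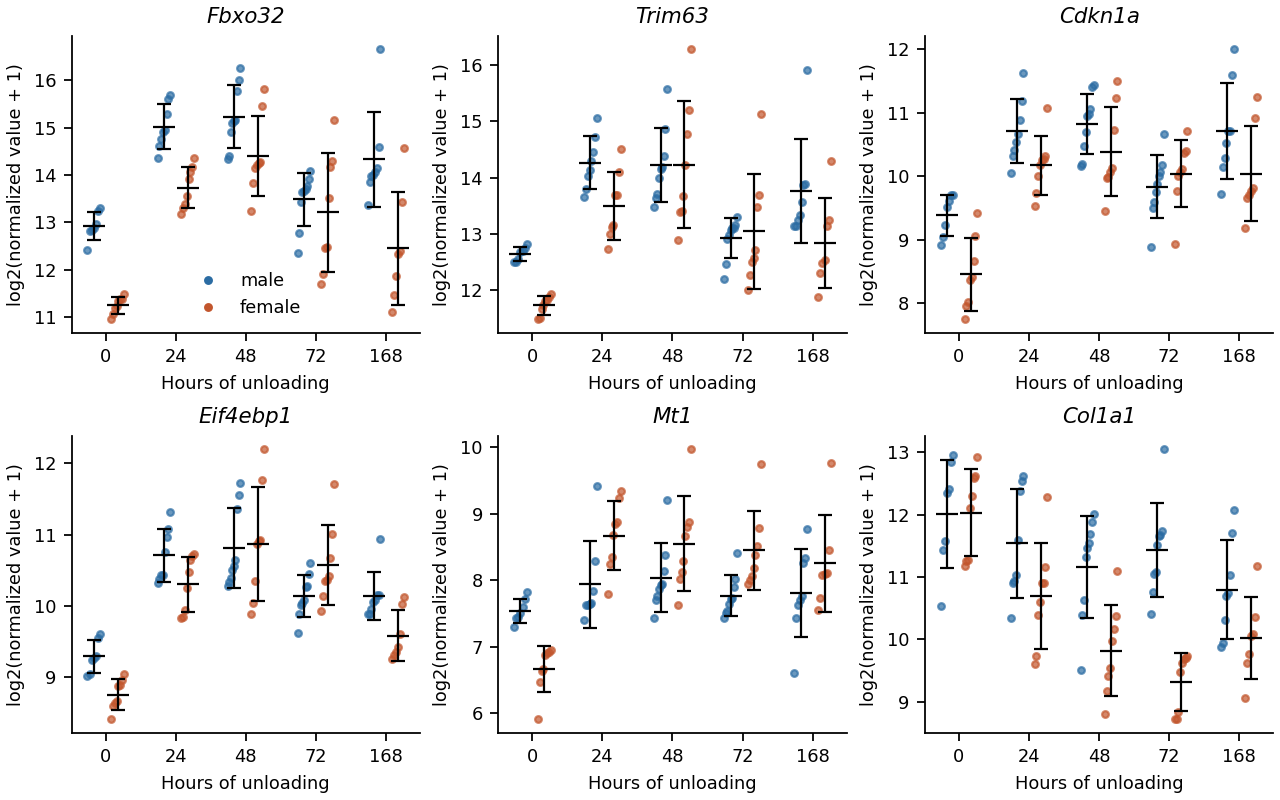
Level of Fbxo32, Trim63, Cdkn1a, Eif4ebp1, Mt1 and Col1a1 (log2 of the normalized value plus 1, vertical axis) in each library by hours of unloading (h, horizontal axis), with the mean and SD. Levels cannot be compared between the sexes, whose tables were normalized separately.

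In females Fbxo32 rose after 24 h by 2.49 ± 0.42 (4.2e-05), from a mean of 2446 ± 294 to 14225 ± 4338 (SD, n = 8 each), and Trim63 by 1.77 ± 0.39 (0.001). The FoxO factors Foxo1 and Foxo3, which switch on both ligases, rose by 1.36 ± 0.27 (0.00035) and 0.82 ± 0.13 (1.4e-05), Psmd8 by 1.21 ± 0.17 (2.2e-06), Sqstm1 by 1.28 ± 0.20 (1.4e-05), Eif4ebp1 by 1.55 ± 0.25 (1.8e-05), Cdkn1a by 1.72 ± 0.29 (4.5e-05) and Eda2r by 2.50 ± 0.34 (1.4e-06). Glucocorticoid targets Glul and Tsc22d3 rose by 1.57 ± 0.16 (4.5e-09) and 1.24 ± 0.17 (1.7e-06), Fkbp5 rose 6.52-fold (9.5e-09), and the clock gene Per1 by 1.37 ± 0.26 (0.00018). The metallothionein genes Mt1 and Mt2, close copies of each other, rose 4.01-fold (3.5e-06) and 5.35-fold (6.1e-06). Lcn2, an iron-binding acute phase protein, rose by 4.22 ± 0.38, Odf3l2 by 4.03 ± 0.52, Pnmt by 3.45 ± 0.33 and Arrdc2 by 2.87 ± 0.34.

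Lower genes of females at 24 h included Nmrk2, which makes NAD in muscle, at −2.56 ± 0.40, Mdga1 at −2.29 ± 0.36, and Mrtfa, a coactivator that answers to actin tension, at −1.82 ± 0.29. Rpsa-ps2, a copy of a ribosomal gene whose reads are hard to assign, was at −2.14 ± 0.50. Col15a1, Col6a3 and Col6a2 fell by 1.54 ± 0.20 (7.1e-07), 1.13 ± 0.18 (1.6e-05) and 1.20 ± 0.22 (0.00014), Col1a1 by 1.33 ± 0.33 (0.0032, 7 of 8 libraries), Irs1 by 1.58 ± 0.31 (0.00024) and Ppargc1b by 1.45 ± 0.26 (9.9e-05). In females at 24 h 1530 genes of 11068 were higher and 1205 lower. With quantile normalization 1160 were higher and 1539 lower, and with scaling to the library total 913 and 1382. By list (adjusted over the list alone in parentheses), 15 of 22 atrophy genes rose (15, with 1 lower), all 32 proteasome genes rose (32), 12 of 23 autophagy genes rose (14), 11 of 15 glucocorticoid genes rose (13), 12 of 22 antioxidant genes rose (14), 9 of 30 TCA cycle and fatty acid genes rose (10), and 1 of 29 matrix genes rose and 16 fell (1 and 19). The adjusted p = 0.113 with an estimated correlation for the glucocorticoid list, 0.134 for the atrophy, proteasome, autophagy and antioxidant lists, 0.401 for the matrix list and 0.968 for the TCA cycle list. Of 5 tenocyte markers, with a median of −0.65, 1 fell (0 adjusted over the list alone, adjusted p = 0.69 with an estimated correlation). Tnmd was at −0.89 ± 0.37 (0.079, 7 of 8 libraries lower), which was 0.0368 without female 24 h replicate 2.

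At 48 h Fbxo32 was up in females by 3.16 ± 0.42 (3.8e-07) and Trim63 by 2.50 ± 0.39 (4.9e-06), and mean Fbxo32 was 25517 ± 16807 (SD, n = 8). Proteasome genes Psmd2 and Psmd8 rose by 1.34 ± 0.12 (1.7e-10) and 1.68 ± 0.17 (1.6e-09), Sqstm1 by 1.63 ± 0.20 (8.4e-08), and the mitophagy receptor Bnip3 by 1.14 ± 0.16 (1.3e-06). Hdac4 and Runx1, which rise after loss of nerve supply, rose by 0.84 ± 0.11 (1.2e-07) and 1.47 ± 0.35 (0.0011), and Ache, which ends the nerve signal, fell by 1.17 ± 0.27 (0.00064). Eif4ebp1 rose by 2.11 ± 0.25 (3.6e-08), Igfbp3 by 1.24 ± 0.20 (9.7e-06), Sod1 by 0.98 ± 0.14 (7.3e-07) and Mt1 by 1.88 ± 0.28 (2.9e-06). The growth factor Igf1 fell by 0.96 ± 0.26 (0.0033) and its binding protein Igfbp5 by 1.54 ± 0.25 (6.4e-06). Odf3l2 rose by 3.58 ± 0.52 and Eda2r by 3.22 ± 0.34, while Fgfbp1, which keeps motor endplates intact, fell by 3.23 ± 0.29, and Nrep, a neuronal regeneration protein, by 2.91 ± 0.23.

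Among lower genes in females at 48 h, Casq2 and Casq1 fell by 1.98 ± 0.26 (3.1e-07) and 1.49 ± 0.21 (6.6e-07), Myh2 by 2.28 ± 0.42 (5.2e-05) and Myl2 by 1.88 ± 0.56 (0.0069). Sdhd and Cyc1 of the respiratory chain fell by 0.72 ± 0.12 (1.2e-05) and 0.76 ± 0.14 (7.3e-05), and Idh3a of the TCA cycle by 0.67 ± 0.11 (7.5e-06). Col1a1 fell by 2.21 ± 0.33 (2.6e-06), Col3a1 by 1.66 ± 0.29 (2.2e-05) and Col6a2 by 1.77 ± 0.22 (1.3e-07). Of the markers of tenocytes, the cells of tendon, Tnmd fell by 1.73 ± 0.37 (0.00036) and Comp by 1.42 ± 0.41 (0.0056), as did Lum, a marker of fibro-adipogenic progenitors, by 1.09 ± 0.22 (0.00012).

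The counts in females at 48 h were 2325 higher and 1890 lower. By list (adjusted over the list alone in parentheses), 17 of 22 atrophy genes rose and 1 fell (17 and 1), all 32 proteasome genes rose (32), 15 of 23 autophagy genes rose (16), 14 of 15 glucocorticoid genes rose (14, with 1 lower), 2 of 29 matrix genes rose and 21 fell (2 and 22), 16 of 42 oxidative phosphorylation genes fell (16), and 5 of 12 slow fibre genes fell (5). Of the markers, 4 of 5 tenocyte genes fell (5) and 3 of 7 fibro-adipogenic progenitor genes fell (3). The adjusted p = 0.112 with an estimated correlation for the atrophy, proteasome, autophagy and glucocorticoid lists, 0.37 for the matrix list, 0.423 for the tenocyte list, 0.581 for the slow fibre and progenitor lists and 0.629 for oxidative phosphorylation.

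At 72 h Fbxo32 was up in females 3.89-fold (0.00052) and Trim63 2.49-fold (0.0097), and mean Fbxo32 was 13177 ± 11557 (SD, n = 8). Proteasome genes Psmc3, Psmd8 and Psma7 rose by 0.99 ± 0.09 (7.8e-10), 1.70 ± 0.17 (3.1e-09) and 1.32 ± 0.14 (9.2e-09), the lysosomal protease Ctsd by 0.88 ± 0.13 (2.3e-06), Fbxo31 by 0.97 ± 0.12 (1.8e-07), Eif4ebp1 by 1.82 ± 0.25 (8.2e-07), Cdkn1a by 1.59 ± 0.29 (7.8e-05), Fkbp5 by 1.95 ± 0.28 (2.0e-06) and Mt1 by 1.79 ± 0.28 (1.0e-05). Arrdc2 rose by 2.62 ± 0.34. Actc1 fell by 4.15 ± 0.41, Fgfbp1 by 3.23 ± 0.29, Nrep by 3.01 ± 0.23 and Myh2 by 2.85 ± 0.42. Collagen genes Col1a1, Col1a2 and Col3a1 fell by 2.72 ± 0.33 (1.5e-07), 2.32 ± 0.32 (1.0e-06) and 1.79 ± 0.29 (1.2e-05), and the matrix gene Fn1 by 1.56 ± 0.21 (7.1e-07). Casq2 fell by 1.97 ± 0.26 (6.1e-07), Myl1 by 0.88 ± 0.17 (0.00014), Sdhc and Ndufs1 of the respiratory chain by 0.63 ± 0.12 (0.00018) and 0.55 ± 0.11 (0.00039), and the growth factor Igf2 by 0.74 ± 0.11 (2.2e-06).

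Some markers of other cells were also lower in females at 72 h. The red blood cell genes Hbb-bt and Alas2 fell by 1.09 ± 0.31 (0.0071) and 0.95 ± 0.30 (0.016), the tenocyte genes Tnmd and Comp by 2.39 ± 0.37 (7.6e-06) and 1.73 ± 0.41 (0.0014), and Lum by 1.45 ± 0.22 (3.2e-06). With the mean of the tenocyte markers as a covariate 1280 genes were called. The calls of Fbxo32, Trim63 and Hbb-bt ended, as the estimates shrank (Fbxo32 1.961 ± 0.42 to 1.08 ± 0.47, Trim63 1.31 ± 0.39 to 0.42 ± 0.43, Hbb-bt −1.09 ± 0.31 to −0.69 ± 0.38) and the standard errors grew. Psmc3, Ctsd, Eif4ebp1, Mt1, Col1a1 and Tnmd kept their calls with smaller estimates (Psmc3 0.99 to 0.88, Col1a1 −2.72 to −1.51, Tnmd −2.39 to −0.97). Tnmd is itself a member of the covariate. Without a covariate 1861 genes were higher and 1463 lower, and with scaling to the library total 2433 and 972. By list (adjusted over the list alone in parentheses), 30 of 32 proteasome genes rose (32), 12 of 22 atrophy genes rose (14), 14 of 23 autophagy genes rose (16, with 1 lower), 10 of 15 glucocorticoid genes rose (12), 21 of 29 matrix genes fell (22), 16 of 42 oxidative phosphorylation genes fell (21), 5 of 13 mitochondrially encoded genes fell (6), and 6 of 12 slow fibre genes fell (6). Of the markers 5 of 5 red blood cell genes (5), 4 of 5 tenocyte genes (4) and 3 of 7 progenitor genes (4) fell. The adjusted p = 0.189 with an estimated correlation for the proteasome and autophagy lists, 0.204 for glucocorticoid, 0.229 for matrix, 0.3 for atrophy, 0.314 for tenocyte and progenitor markers, 0.454 for oxidative phosphorylation, slow fibre and red blood cell genes, and 0.5262 for mitochondrially encoded genes.

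After 168 h targets of glucocorticoids, hormones that break down muscle protein, were up in females, and theirs was the only list of any comparison with 0 h that passed camera with an estimated correlation (adjusted p = 0.0027). Of its 15 genes 14 rose (14 adjusted over the list alone), with a median change of 1.33. The female 168 h libraries were all of another library set than the controls. At 48 h, where the female libraries shared the set of the controls, this list did not pass. Glul rose by 1.74 ± 0.16 (1.4e-09), Fkbp5 by 2.66 ± 0.29 (5.0e-08), Tsc22d3, which mediates the anti-inflammatory effect of glucocorticoids, by 1.33 ± 0.17 (1.6e-06), Cebpd by 2.58 ± 0.40 (2.3e-05) and Ddit4 by 2.90 ± 0.51 (0.00016). Foxo1 was up by 1.26 ± 0.28 (0.0029), Cdkn1a by 1.58 ± 0.30 (0.00047), the stress sensor Gadd45g by 2.30 ± 0.34 (1.1e-05) and Mt1 by 1.59 ± 0.29 (0.00034). Fbxo32 was at 1.21 ± 0.44 (0.07, 6 of 7 libraries higher) and Trim63 at 1.11 ± 0.41 (0.072), and without female 168 h replicate 3 these were called (0.0318 and 0.0455). Col1a1, Sparc and Col15a1 fell by 2.01 ± 0.34 (0.00012), 1.20 ± 0.22 (0.00034) and 1.26 ± 0.21 (5.6e-05), Casq2 by 1.51 ± 0.27 (0.0002), Myl2 by 2.33 ± 0.57 (0.006), Actc1 by 3.23 ± 0.43 (2.1e-06), Bdh1 by 2.14 ± 0.41 (0.00052) and Kdr by 0.90 ± 0.17 (0.00047). Odf3l2 and Arrdc2 rose by 3.82 ± 0.54 and 3.21 ± 0.35, Actn3 by 0.64 ± 0.15 (0.0037) and Chrnb1 by 0.84 ± 0.12 (5.4e-06).

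In females at 168 h 697 genes were higher and 485 lower, and with quantile normalization 580 and 678. The 1182 in all became 2054 with the compared groups alone, 1793 with the length trend as a covariate and 3120 with array weights. Eif4ebp1 rose by 0.83 ± 0.25 (0.029), which was 0.078 without female 168 h replicate 7. By list (adjusted over the list alone in parentheses), 4 of 32 proteasome genes rose (9), 9 of 22 atrophy genes rose (12), 5 of 23 autophagy genes rose (10), 15 of 29 matrix genes fell (18), 4 of 12 slow fibre genes fell (7), and 4 of 30 TCA cycle and fatty acid genes fell (6). The adjusted p = 0.138 with an estimated correlation for the atrophy list, 0.348 for matrix, 0.46 for autophagy and slow fibre genes, 0.581 for the TCA cycle list and 0.612 for the proteasome list. Of 5 tenocyte markers, with a median of −0.68, Tnmd fell, by 1.39 ± 0.39 (0.015; 1 adjusted over the list alone, adjusted p = 0.487 with an estimated correlation).

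**Figure D3:**
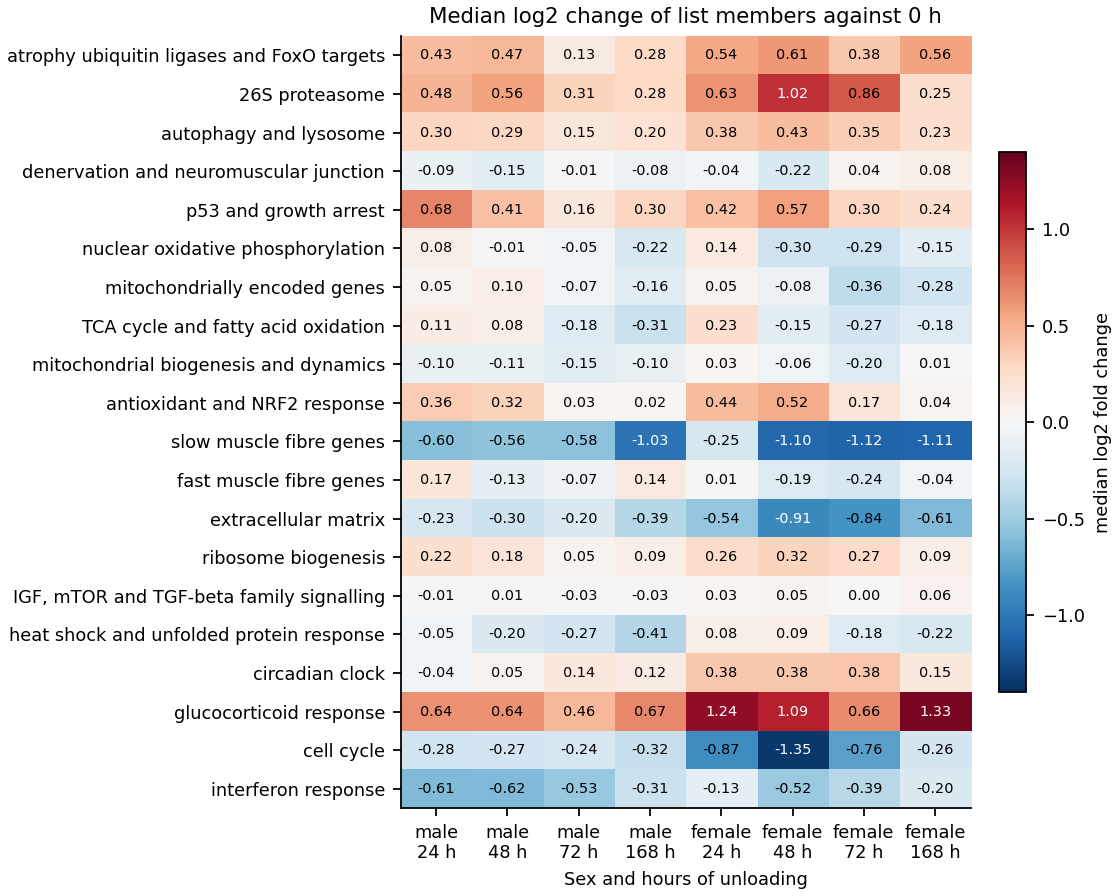
Median log2 change (colour) of the members of 20 gene lists (vertical axis) at 24, 48, 72 and 168 h of unloading (horizontal axis) against 0 h in males and females. The median of the proteasome list in females at 48 h was 1.02.

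For the remaining lists, among 16 circadian genes in males 2, 3, 1 and 2 rose in order of time and 1 fell at 24 h, and among 15 in females 4, 4, 5 and 2 rose and 1 fell at 24 h and 1 at 48 h, with the same counts adjusted over the list alone. Of the denervation list 2 rose and 3 fell in males at 24 h (3 and 3 adjusted over the list alone), and 4 rose and 6 fell in females at 48 h (4 and 6). For IGF, mTOR and TGF-beta signalling these were 5 and 4 (5 and 4), and 7 and 6 (7 and 6 adjusted over the list alone). Of 15 genes of mitochondrial biogenesis 4 fell and 1 rose in males at 24 h (4 and 1 adjusted over the list alone), and 4 fell and 3 rose in females at 48 h. Of 14 fast fibre genes 6 fell in females at 48 h (6 adjusted over the list alone), and of 5 cell cycle genes 3 fell in males at 24 h (3, with 2 higher). Of 9 endothelial markers 2 rose and 2 fell in males at 24 h, and 1 of each in females at 24 h. Of 8 adipocyte markers 2 rose in females at 168 h (2 adjusted over the list alone). Of 11 macrophage markers none was called by limma in males at 24 h, where 1 had an unadjusted p under 0.05, and 1 rose in females at 168 h (1). Without male 0 h replicate 1 the macrophage marker Adgre1 was called in males at 24 h, at −0.64 (0.048). Times not listed here also held calls. In females at 72 h the macrophage marker Mrc1 fell by 0.90 ± 0.27 (0.0092). The endothelial markers Kdr and Emcn fell then by 0.94 ± 0.17 (4.7e-05) and 0.51 ± 0.17 (0.021), while Cldn5 was at 0.48 ± 0.22 (0.091). The cell cycle genes Mcm2 and Aurka fell by 0.91 ± 0.18 (0.00023) and 0.76 ± 0.23 (0.011), and Pcna was at 0.02 ± 0.11 (0.91). Counts of libraries are not given for these genes. No Schwann cell marker of 5 was called by limma at any time, and 0 had an unadjusted p under 0.05. Of 2 satellite cell markers in females, Chodl rose at 24 h, by 0.58 ± 0.16 (0.0063, 7 of 8 libraries). No neutrophil marker was in either table.

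**Figure D4:**
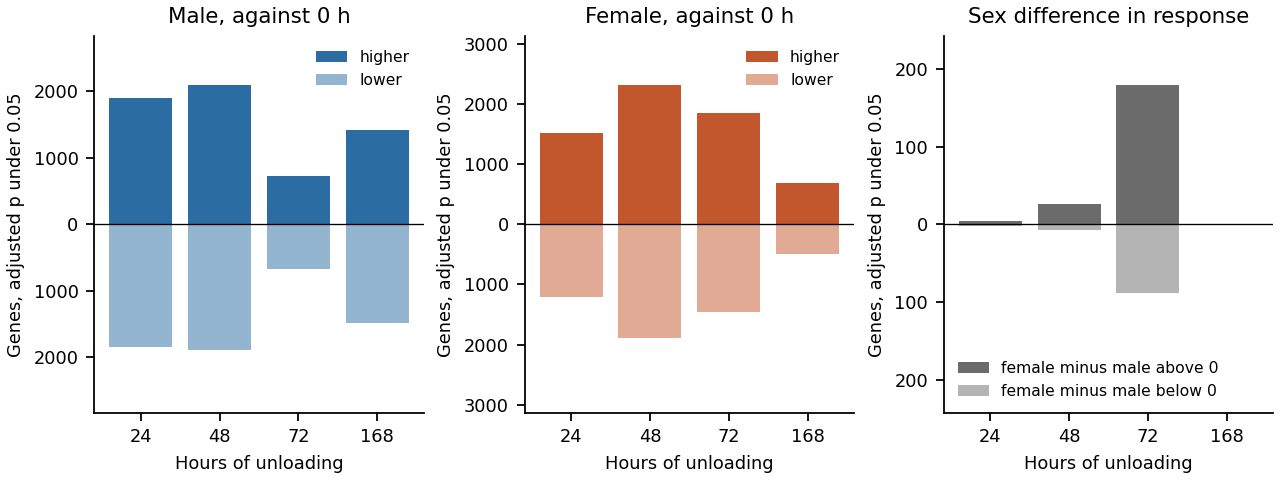
Number of genes called by limma (vertical axis, higher above and lower below 0) at each time of unloading (h, horizontal axis) in males, in females and for the difference between the sexes. At 72 h 268 genes differed between the sexes.

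The sexes changed much alike. Over the 10964 genes in both tables the correlation between male and female changes was 0.74 at 24 h, 0.84 at 48 h, 0.68 at 72 h and 0.75 at 168 h (Pearson, between genes, which are not independent). Its SD over resampled libraries was 0.0683, 0.0480, 0.0670 and 0.0515. Genes higher in both sexes numbered 1063, 1490, 529 and 462, where 249, 417, 114 and 83.7 would be shared by chance, and genes lower in both 750, 1099, 365 and 363, where 172, 282, 80.05 and 56.9 would be. Genes called in opposite directions numbered 0, 1, 2 and 0, where 415, 687, 192 and 140 would be by chance.

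At 24 h the change differed between females and males in 6 genes, and 651 had an unadjusted p under 0.05. Prodh, which breaks down proline, changed more in females by 1.28 ± 0.22 (0.0016), Inmt, a methyl transferase, by 1.29 ± 0.28 (0.029) and Rilpl1 by 0.60 ± 0.13 (0.026), while Rhobtb1 was at −0.94 ± 0.21 (0.034). Leaving out single libraries, the calls of Inmt, Rilpl1 and Rhobtb1 ended, Rhobtb1 reaching 0.105 and Rilpl1 reaching 0.079 without male 0 h replicate 7. The ligases were not called, with Fbxo32 at 0.39 ± 0.54 (0.9) and Trim63 at 0.15 ± 0.50 (0.96). These standard errors leave room for a difference in either direction. Mt1 was at 1.61 ± 0.39 (0.079), which was 0.0197 without male 24 h replicate 5. The split was 4 higher and 2 lower, with quantile normalization 1 and 1, and with scaling to the library total 5 and 1. The count was 2 without male 0 h replicates 5 or 7 or female 24 h replicates 1 or 2, 3 without female 0 h replicates 1 or 2, 10 without male 24 h replicate 7 and 12 without female 24 h replicate 5.

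At 48 h the difference was called for 33 genes, 26 higher and 7 lower, and 1329 had an unadjusted p under 0.05. Stab2, a scavenger receptor of endothelium, was higher in the female change by 1.53 ± 0.23 (6.9e-05), the peptidase gene Lvrn by 1.38 ± 0.28 (0.0099), Inmt by 1.25 ± 0.27 (0.015) and Odf3l2 by 2.65 ± 0.61 (0.025). Rhobtb1 was lower by 1.05 ± 0.20 (0.0052), Nrep by 1.52 ± 0.33 (0.015), the myotonic dystrophy kinase gene Dmpk by 0.74 ± 0.17 (0.025), the matrix gene Sparcl1 by 0.65 ± 0.15 (0.025) and the lysosomal gene Aga by 0.60 ± 0.15 (0.038). Without female 0 h replicate 7 Odf3l2 was at 0.061, and single libraries also ended the calls of Dmpk, Sparcl1 and Aga. The proteasome gene Psmd2 differed by 0.68 ± 0.14 (0.01), and it was the only one of 32 (24 adjusted over the list alone, adjusted p = 0.414 with an estimated correlation). Fbxo32 was at 0.85 ± 0.53 (0.52). With quantile normalization 18 genes were higher and 9 lower. The count was 94 without female 48 h replicate 1, 58 without replicate 2 and 17 without replicate 7, 20 without female 0 h replicates 1 or 7 or female 48 h replicate 6, 21 without female 48 h replicates 4 or 5, and 50 without male 48 h replicate 2 or female 0 h replicate 3.

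At 72 h 268 genes differed, 180 higher and 88 lower, and 1885 had an unadjusted p under 0.05. In 262 of them the female change was the larger, and 181 were called in females alone. Many proteasome genes rose more in females, Psmd2 by 0.82 ± 0.14 (0.00059), Psmc3 by 0.61 ± 0.11 (0.00094), Psmd8 by 0.93 ± 0.20 (0.0074) and Psmb3 by 0.82 ± 0.19 (0.0098), in all 17 of 32 (29 adjusted over the list alone, adjusted p = 0.233 with an estimated correlation). Ctsd rose more by 0.74 ± 0.15 (0.0043), Fbxo31 by 0.65 ± 0.16 (0.015), Igfbp3 by 1.14 ± 0.27 (0.012), Fkbp5 by 1.37 ± 0.35 (0.019) and Mt1 by 1.56 ± 0.38 (0.014). Some collagen genes fell more in females, Col1a1 by 2.14 ± 0.53 (0.014), Col1a2 by 1.90 ± 0.47 (0.014) and Col15a1 by 1.04 ± 0.26 (0.019), in all 9 of 29 matrix genes (16 adjusted over the list alone, adjusted p = 0.282 with an estimated correlation). Nrep fell more by 2.05 ± 0.33 (0.00035), Nmrk2 by 2.73 ± 0.63 (0.011), Lum by 1.32 ± 0.26 (0.0034) and the tenocyte gene Tnmd by 2.22 ± 0.51 (0.0098). The difference in Fbxo32 was 2.64-fold (0.14), that in Trim63 1.04 ± 0.49 (0.25) and that in Cdkn1a 1.14 ± 0.39 (0.1), the last at 0.0434 without female 72 h replicate 8.

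Several of the genes that differed at 72 h were sensitive to single libraries. Odf3l2 (2.24 ± 0.61, 0.033) was at 0.057 without female 72 h replicate 4, Actc1 (−2.11 ± 0.60, 0.041) at 0.083 without male 0 h replicate 7, and Sod1 (0.61 ± 0.18, 0.047) at 0.117 without female 72 h replicate 4. Rpl17-ps3 (3.005 ± 0.67, 0.0076) and Rpl10-ps5 (1.86 ± 0.54, 0.045) are copies of ribosomal genes whose reads are hard to assign. The adipocyte hormone gene Lep differed by 2.85 ± 0.72 (0.017), and the median of 8 adipocyte markers by 1.25 (1 called, 5 adjusted over the list alone, adjusted p = 0.287 with an estimated correlation). With the tenocyte covariate no gene was called by limma, and the median of the matrix list went from −0.75 to −0.43 (median standard error 0.272 before and 0.269 after). With quantile normalization 113 were higher and 93 lower, with scaling to the library total 184 and 42, and with libraries thinned to one depth 60 and 50. The count was 119 without female 72 h replicate 4, 171 without replicate 7 and 444 without replicate 8, 163 without female 0 h replicate 1, and 155, 176 and 149 without male 0 h replicates 3, 5 and 7.

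At 168 h 2 genes differed, of 424 with an unadjusted p under 0.05. One was Rhobtb1, at −1.15 ± 0.21 (0.0058), called in every fit that left out a library. Fbxo32 was at −0.20 ± 0.55, but 0.13 without male 168 h replicate 8 and 0.02 without female 168 h replicate 3, and Trim63 had no clear direction, with a standard error of 0.50. Fkbp5 differed 3.04-fold (0.067), which was 0.00545 without female 0 h replicate 4, and the glucocorticoid list had a median of 0.56 (2 of 15 higher adjusted over the list alone, adjusted p = 0.0872 with an estimated correlation). Of 8 adipocyte markers, with a median of 1.18, none was called by limma (8 with an unadjusted p under 0.05, 8 higher adjusted over the list alone), and the list did not pass either (adjusted p = 0.0872 with an estimated correlation). The count was 13 without female 168 h replicate 2, 11 without male 168 h replicate 8, 7 without female 0 h replicate 6, 5 without male 0 h replicate 4 or female 168 h replicate 7, and 1 without male 0 h replicates 1, 5 or 6, male 168 h replicates 5 or 6, female 0 h replicates 1 or 7 or female 168 h replicates 4 or 6.

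The authors' own DESeq2 sheet called 3891, 4134, 1611 and 3053 genes in males and 3175, 4908, 3648 and 1634 in females in order of time. Of the genes called here, 97.4% to 99.8% were also called there.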

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

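The response score of the male 72 h libraries by library set, the covariates for transcript length and for tenocyte markers, and leaving out single libraries were tests chosen only after the results were seen, and the margin used to read the tenocyte covariate was set after its value was seen.

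Single libraries stood apart from their group in 26 of 220 gap tests (11.8%), each of 1 measure in 1 of the 10 groups. Chance passes about 1 of 20 such tests, and the measures are not independent of each other. The median correlation with the own group was 0.866 in female 72 h replicate 5, 0.916 in female 0 h replicate 7, 0.947 in female 168 h replicate 7, 0.967 in male 72 h replicate 4, 0.969 in male 48 h replicate 2 and 0.970 in male 24 h replicate 5. The trend of the signal with transcript length was −0.160 in female 48 h replicate 5. Male 168 h replicate 8 stood apart on the log2 scale in Fbxo32 (16.66), Trim63 (15.92) and Eif4ebp1 (10.94), and male 72 h replicate 9 in Col1a1 (13.04). Ddit4 was at 8.64 in female 0 h replicate 6, Gadd45a at 10.45 in female 72 h replicate 4, and Mstn at 8.85 in female 72 h replicate 5 and 9.50 in female 168 h replicate 2. Ppargc1a was at 10.24 in male 0 h replicate 7, 9.39 in female 24 h replicate 8 and 7.78 in female 48 h replicate 5. The near-identical metallothionein genes stood apart most often: Mt1 in female 0 h replicate 1 (5.91), female 72 h replicate 7 (9.74), female 168 h replicate 7 (9.76) and male 24 h replicate 5 (9.41), and Mt2 in male 0 h replicate 1 (5.37), male 48 h replicate 2 (9.11), female 72 h replicate 7 (9.32) and female 168 h replicate 7 (9.27).

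The change with unloading differed between the sexes, by a test of the difference itself, in 6 genes at 24 h, 33 at 48 h, 268 at 72 h and 2 at 168 h. Leaving out 1 library gave 2 (without male 0 h replicate 5) to 12 (without female 24 h replicate 5) at 24 h, 17 to 94 (without female 48 h replicates 7 and 1) at 48 h, 119 to 444 (without female 72 h replicates 4 and 8) at 72 h, and 1 (without male 0 h replicate 1) to 13 (without female 168 h replicate 2) at 168 h. Of 100 splits of the libraries at each time, the real one included, 2, 1, 2 and 3 gave as many genes. The highest of the other splits gave 7, 1, 1637 and 9. Chance alone is argued against at 48 h. At 24, 72 and 168 h another split gave more genes than the real one, so chance is made less likely there but cannot be excluded. The 1637 genes of one other split at 72 h, several times the real 268, point to a structure of the samples whose nature was not tested. Such splits also cannot tell a sex difference from the library sets. Male changes were between sets at 24 and 48 h, and at 72 h for most libraries. Female changes were between sets at 24, 72 and 168 h. Sex and library set are thus confounded, at least in part, at every time.

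The sex difference, female minus male on the log2 scale, was 1.29 for Inmt, 1.28 for Prodh, 0.60 for Rilpl1 and −0.94 for Rhobtb1 at 24 h. At 48 h it was 2.65 for Odf3l2, 1.53 for Stab2, 1.38 for Lvrn, 1.25 for Inmt, −1.52 for Nrep, −1.05 for Rhobtb1, −0.74 for Dmpk, −0.65 for Sparcl1 and −0.60 for Aga. At 72 h it was 2.24 for Odf3l2, 1.56 for Mt1, −2.73 for Nmrk2, −2.22 for Tnmd, −2.14 for Col1a1, −2.11 for Actc1 and −2.05 for Nrep, and, with reads hard to assign between copies, 3.005 for Rpl17-ps3 and 1.86 for Rpl10-ps5. At 168 h it was −1.15 for Rhobtb1.

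In males fewer genes were called at 72 h (1392) than at 24, 48 or 168 h, and the sex difference was called for the most genes (268) at that time. With the tenocyte covariate no sex difference was called at 72 h, and what that covariate takes up besides tendon was not tested. Lower depth of the female 72 h libraries is argued against as the whole cause. With every library thinned to one depth 110 genes differed, above the 33 at 48 h without thinning, the bound set beforehand. Thinning did lower the count at 72 h, from 268. For a trend with transcript length neither outcome set beforehand was met. With that covariate the count neither fell below 33 nor stayed within 1.5 times, but was 487. The bound did not allow for a trend that hides differences. The rise argues against the trend as the source of these calls, but the trend does affect their number. The library set stays open: the 2 male 72 h libraries made with the controls had a mean response score (mean change from 0 h, signed by direction, over the genes called in females at 72 h) of 0.312, against 0.216 for the other 7, as this explanation needs (means by time 0.311, 0.361, 0.237 and 0.310), and the only 48 h library of the set of those 7 had 0.232, the lowest of its group, yet 1 of the 2, at 0.259, lay within the range of the 7 (0.161 to 0.295), and the exact two-sided permutation p was 0.111, where 0.0278 was the smallest possible. All 8 female 72 h libraries were of another set than the female controls, so no such split by set was possible in females. The female change, the larger one in 262 of the 268 genes, was thus wholly between sets. A technical difference between library sets in either sex may therefore account for part of the pattern. A later or longer response of females, for which sex is the design's own biological explanation, stays open as untested.

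Some matrix genes fell more in females at 72 h, with a list median of −0.84 (21 of 29 lower) and a sex difference of −0.75 (9 lower). A library trend with transcript length is argued against, since the female median was −0.83 with that covariate. More tendon tissue in the female control samples stays open and cannot be told apart from a fall of matrix genes within muscle, because tenocyte markers are themselves matrix genes: with their mean as a covariate the female median was −0.48 (13 lower, 2 higher; median standard error 0.211, before 0.198). The sex difference was then −0.43, and its calls ended as the estimate shrank from −0.75 while the median standard error went from 0.272 to 0.269. Tendon in the samples may thus account for part of the fall, and a sex difference in matrix genes of the muscle itself stays open as untested.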

How the results depend on the processing

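Alternatives chosen after seeing the data were the pseudocount of 10, the mean of at least 50, quantile normalization, total scaling, array weights, both covariates, leaving out poorly correlated female libraries and leaving out each library in turn. In edgeR, relative log expression and the comparison of no filter with an expression filter were not run, and neither was DESeq2 for calls or correlations, because the values are not counts. Counts against 0 h stayed within 1.5 times under every alternative except those named here, and under leaving out any 1 library. The correlations between the sexes moved by less than 1 SD under the alternatives run for them. Thinned libraries, the compared groups alone, the tenocyte covariate and any leaving out of libraries were not among these. For each value below the cause was not tested, unless stated. Depth limits the sex-difference counts, as the thinned values show.

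With a log2 change of at least 1, a stricter threshold, fewer genes pass by construction: 205, 248, 67 and 159 in males, 353, 626, 381 and 204 in females in order of time, 12 and 66 for the sex difference at 48 and 72 h, and 42, 0, 11 and 37 for the direct comparisons (male 72 with 48 h, male 168 with 72 h, and the same in females). None passed in males at 168 against 72 h, where limma called 38 without that threshold. With fewer libraries by construction, male 72 h gave 516 with those of the control set alone and 816 with the others alone.

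With models of the compared groups alone, and so fewer libraries for the variance, female 168 h gave 2054, the sex difference at 24 h 14, and the direct comparisons 563, 11, 4 and 199. With libraries thinned to one depth, the sex difference gave 19, 110 and 1 at 48, 72 and 168 h, and female 72 against 48 h gave 30. Without the least correlated library of each group, the sex difference gave 504 and 6 at 72 and 168 h, male 168 against 72 h 1026 and female 72 against 48 h 41. The preset correlation of 0.01 called 134 list tests instead of 1.

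With array weights, male 72 h gave 2103, female 168 h 3120, the sex difference 29, 135, 972 and 72 in order of time, male 168 against 72 h 630, female 72 against 48 h 206 and female 168 against 72 h 843. With the length trend as a covariate, female 168 h gave 1793, the sex difference 55, 487 and 10 at 48, 72 and 168 h, and the direct female comparisons 223 and 797. With quantile normalization, the sex difference gave 2 and 1 at 24 and 168 h, and female 72 against 48 h 38. Scaling to the total gave 11 for the sex difference at 168 h, 85 for male 168 against 72 h and 2 list tests. Of 470 list medians, 46 changed sign with quantile normalization or total scaling. Without poorly correlated female libraries, the sex difference gave 813 and 7 at 72 and 168 h, and female 168 against 72 h 711. A pseudocount of 10 and a mean of at least 50 each gave 1 for the sex difference at 168 h.

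With the tenocyte covariate, female 72 h gave 1280 and the sex difference at 72 h 0, and Fmod (0.35) and Thbs4 (0.36) in females at 72 h reversed; both are members of the covariate, which by construction takes up their change.

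Leaving out each library in turn gave 515 to 1357, 0 to 124, 3 to 334 and 174 to 510 for the direct comparisons, and 2 to 12, 17 to 94, 119 to 444 and 1 to 13 for the sex difference in order of time. No called named gene changed sign in these fits, but in order of time 17 of 81, 10 of 91, 19 of 61 and 10 of 83 lost their call in some fit in males, 7 of 77, 8 of 97, 10 of 100 and 16 of 65 in females, 3 of 4, 5 of 12, 10 of 29 and 0 of 1 for the sex difference, and 11 of 49, 10 of 10, 8 of 9 and 9 of 29 in the direct comparisons.

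Most named genes kept their direction and their side of the threshold. Those that kept their direction and stopped being called, and those that became called, numbered 61 and 15 (2021 held) with libraries thinned to one depth, 61 and 50 (1986) with the compared groups alone, 67 and 77 (1953) without the least correlated libraries, 47 and 23 (2027) with quantile normalization, 44 and 23 (2030) with scaling to the total, 18 and 165 (1914) with array weights, 19 and 67 (2011) with the length trend as a covariate, 30 and 37 (1219) without poorly correlated female libraries, 70 and 3 (181) with the tenocyte covariate, 35 and 4 (99) with the male 72 h libraries of the control set alone, 17 and 0 (121) with the others alone, 3 and 0 (131) without the one male 48 h library of another set, 4 and 5 (2088) with a pseudocount of 10, and 0 and 0 (2089) with a mean of at least 50.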

Other observations

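The direct comparisons of 72 h with 48 h and of 168 h with 72 h, and the levels of Xist by correlation, were tests chosen after the results were seen. The direct comparisons of females were wholly between library sets and those of males largely so, and differences between sets cannot be told apart there from differences between times.

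In males Fbxo32 was lower at 72 h than at 48 h. It fell by 1.75 ± 0.30 (log2 change ± standard error; adjusted p = 0.0011) and Trim63 by 1.30 ± 0.27 (0.0031), each in 9 of 9 libraries. Pdk4, which spares glucose, fell by 1.81 ± 0.46 (0.012), Depp1 by 1.56 ± 0.41, Slc25a34 by 1.44 ± 0.33, the lysosomal protease Ctsl by 0.78 ± 0.11 (0.00028), Eda2r by 1.33 ± 0.29 (0.004), Cdkn1a by 0.98 ± 0.24 (0.011) and Fabp3 by 1.11 ± 0.22 (0.0028). Mrtfa rose by 1.37 ± 0.25 (0.0011), Kcng4 by 1.32 ± 0.28, Mdga1 by 1.30 ± 0.25 and Nmrk2 by 1.64 ± 0.45 (0.019), which was 0.0527 without male 48 h replicate 2. In all 443 genes were higher and 689 lower, and with scaling to the library total 606 and 322. Of the lists (adjusted over the list alone in parentheses) 7 of 22 atrophy genes (11), 15 of 32 proteasome genes (23), 5 of 23 autophagy genes (9), 5 of 15 p53 genes (8), 9 of 30 TCA cycle genes (14) and 7 of 22 antioxidant genes (8) fell, with adjusted p from 0.283 to 0.513 with an estimated correlation. The 1132 genes became 563 with the compared groups alone, 744, 515 and 659 without male 48 h replicates 1, 2 and 6, and 546 without male 72 h replicate 6. Of 100 splits only the real one gave as many, the highest other giving 30, so chance alone is argued against.

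In females 66 genes differed between 72 h and 48 h, 39 higher and 27 lower, with quantile normalization 27 and 11 and with libraries thinned to one depth 14 and 16. The ribosomal gene copy Rpl10-ps5, whose reads are hard to assign, rose by 2.53 ± 0.31 (7.3e-06). Mrtfa rose by 1.18 ± 0.29 (0.045, 6 of 8 libraries) and Lingo3 by 1.11 ± 0.24 (0.027, 7 of 8), and Gadd45a fell by 1.23 ± 0.30 (0.045, 7 of 8), Snhg6 by 0.98 ± 0.18 (0.012) and Pir by 0.96 ± 0.19 (0.025). Without female 72 h replicate 6 none of the last 5 was called (Mrtfa 0.102, Gadd45a 0.104, and 0.0537 for Lingo3, Snhg6 and Pir). Fbxo32 was at −1.20 ± 0.42 (0.17, 7 of 8 libraries lower) and Trim63 at −1.19 ± 0.39 (0.15, 7 of 8), and without female 72 h replicate 4 both were called (0.0391 and 0.0233). The red blood cell markers had a median of −0.88, with none called by limma (5 of 5 with an unadjusted p under 0.05, and 5 lower adjusted over the list alone). The 66 genes became 4 with the compared groups alone, 41 without the least correlated libraries, 206 with array weights and 223 with the length trend as a covariate. The count was 43, 38, 27, 15, 5 and 40 without female 48 h replicates 3 to 8, and 16, 27, 334, 10, 3, 30 and 23 without female 72 h replicates 2 to 8. Of 100 splits 4, the real one included, gave as many, so chance is made less likely but cannot be excluded. The highest other gave 908, several times the real 66, which points to a structure of the samples whose nature was not tested.

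Most proteasome genes were lower in females at 168 h than at 72 h. Psmd2 fell by 0.98 ± 0.12 (5.7e-06), Psma7 by 0.98 ± 0.14 (0.00012) and Psmc3 by 0.63 ± 0.10 (0.00014), each in 7 of 7 libraries. Of 32 genes 27 fell (29 adjusted over the list alone), with a median of −0.58 and an adjusted p = 0.0401 with an estimated correlation, which ranged from 0.0365 with quantile normalization to 0.0607 with scaling to the library total and 0.0902 with the length trend as a covariate. The lysosomal protease Ctsd fell by 0.82 ± 0.13 (0.00022), Akt1 by 1.02 ± 0.21 (0.0027), Slc6a9 by 1.26 ± 0.24 (0.0014), Mllt11 by 1.14 ± 0.18 (0.00019) and Nos1 by 1.10 ± 0.25 (0.0087). The methyl transferase gene Mettl21e rose by 1.81 ± 0.40 (0.0062), Mybph by 1.65 ± 0.39 (0.013, but 0.059 without female 168 h replicate 3), Glul by 0.90 ± 0.16 (0.00082), and the haemoglobin genes Hbb-bt and Hbb-bs, whose copies share reads, by 1.63 ± 0.32 (0.0022) and 1.47 ± 0.29 (0.0023). In all 148 genes were higher and 246 lower, with scaling to the library total 98 and 273 and with the length trend as a covariate 409 and 388. The 394 genes became 199 with the compared groups alone, 843 with array weights, 711 without poorly correlated female libraries, 219 and 237 without female 72 h replicates 4 and 7, and 174 and 232 without female 168 h replicates 3 and 6. Of 100 splits only the real one gave as many, the highest other giving 64, so chance alone is argued against.

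In males 38 genes differed between 168 h and 72 h, 16 higher and 22 lower, and with scaling to the library total 13 and 72. The count was 11 with the compared groups alone, 1026 without the least correlated libraries and 630 with array weights. Mrln, a micropeptide that restrains the calcium pump, rose by 0.72 ± 0.14 (0.027), Klf11 by 0.70 ± 0.16 (0.044), Smim36 by 0.64 ± 0.14 (0.039) and Mstn by 0.59 ± 0.14 (0.045). H19 fell by 0.81 ± 0.17 (0.039), Alpl by 0.73 ± 0.17 (0.044), Aplnr by 0.72 ± 0.16 (0.042) and Sox7 by 0.61 ± 0.14 (0.042). Without male 168 h replicate 8 all 8 calls ended, at 0.0565 for Mrln, 0.0996 for Klf11 and Aplnr, 0.0741 for Smim36, 0.14 for Mstn, 0.0888 for H19, 0.127 for Alpl and 0.105 for Sox7. The count was 58, 14, 3, 9 and 14 without male 72 h replicates 2 to 6, and 6 and 2 without replicates 8 and 9, and 59, 19, 124, 18, 1, 2 and 0 without male 168 h replicates 2 to 8. Of 100 splits only the real one gave as many, the highest other giving 15, so chance alone is argued against.

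For the comparisons with 0 h, too, only the real one of 100 splits gave as many genes. In males the real counts were 3743, 3988, 1392 and 2897 in order of time and the highest others 1524, 2030, 830 and 175. In females these were 2735, 4215, 3324 and 1182, and 1324, 2665, 2155 and 414. Chance alone is argued against for each. Such splits cannot tell unloading from the library set. Only the male 168 h libraries, the female 48 h libraries and 2 male 72 h libraries shared the set of their controls.

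Xist, which silences an X chromosome in females, had a signal of 172 to 1564 (median 893) in the 7 female libraries with a median correlation under 0.95, and of 1181 to 4274 (median 3159.5) in the other 32. The trend with transcript length was −0.350 to −0.143 in the former and −0.175 to 0.246 in the latter.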
